A study of Mus musculus with 6 samples.

How the data were processed

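Total RNA of ventral hippocampus was extracted with Trizol, mRNA was taken by its poly(A) tail, and strand-specific libraries were made by marking the second strand with dUTP, per the labels' protocols. The deposited values are whole-number counts per Ensembl gene, not normalized, in 1 table whose 6 columns match the 6 libraries by name; 0 per-sample columns were left unused. Trimmomatic 0.36, STAR 2.7.10 and featureCounts 2.0.3 and the genome builds mm10 and GRCm39 are named without roles, per the submitters' processing notes. Which build the counts rest on, the annotation release and the strand setting of the counting are not given in the sources used here, so no genome coordinates are printed. A wrong strand setting would lower counts, and reads of near-identical genes could have been split or left out at that step.

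Of the 56941 identifiers deposited, 51948 had a symbol in a list of gene identifiers and 4993 had none; the latter held 0.264 to 0.348% of the counts of a library. Total counts per library were 33448707, 33785112 and 36174442 for overexpression replicates 1 to 3 and 31990842, 38108394 and 30726110 for control replicates 1 to 3. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes with at least 10 counts in the pair was 4.28 to 12.9. The samples are separate mice per the series' design text.

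Groups were taken from the labels. The main test, chosen before the data were examined, was edgeR 4.0.16's quasi-likelihood test (robust) in R 4.3.3, with TMM factors, edgeR's default filter on low counts and group as the only term; 19354 genes were tested. p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken from the F statistic. The common biological coefficient of variation was 0.0866. Negr1 was also tested with a two-sided exact permutation test; 3 libraries against 3 cannot reach a p below 0.1.

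A total of 43 gene lists (synaptic, signalling, stress, metabolic, cell type and region markers) were written before the data were examined and tested with camera of limma 3.58.1 on voom values, with the preset correlation of 0.01, for lists with at least 4 tested members. Camera was repeated with the correlation estimated for each list, and fry was run as a self-contained test. List symbols missing from the symbol table were matched through RefSeq synonyms (assembly GRCm38.p6, used for names only), a step added after a first exploratory run. A further 6 lists were written after the main results had been seen.

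Genes named in the text were chosen by a rule set before the data were examined. It takes Negr1 and the IgLON genes, genes past the threshold with a mean of at least 1 CPM in 1 group, chosen by p and by size of change, and members of the lists that passed; where no member passed, the 2 with the smallest p are given as values. A gene named outside the rule is said to be so.

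The gene test was tested on simulated counts drawn from these libraries' means, with 50 genes changed at each fold among 19056 tested. It recovered 24% at 1.25-fold, 62% at 1.5-fold, 72% at 2-fold and 94% at 4-fold, with 12 false calls among unchanged genes. More genes passed in this simulation than in the real data, which loosens the cutoff that adjustment sets on p. These shares can therefore overstate what the real test would recover. In a simulation with 1 list raised 1.2-fold, that list passed and 0 others without shared members did. The simulated genes varied independently, and in the real libraries each of the 9 other splits into 3 and 3 gave at least 12 lists past the threshold, so the simulation does not give the rate of chance calls here. The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with sample weights, no filter and a stricter filter (1 CPM in 3 libraries), the replicate number as a block, scaling without Negr1 and mitochondrially encoded genes, an adjusted p of 0.1, and leaving out each library in turn. A correction for GC content and list matching without synonyms were added after the data were seen. GC content and length came from the transcripts of a GENCODE mouse annotation, which covered 97.7% of tested genes.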

Results

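Poly(A) RNA sequencing was carried out on the ventral hippocampus of 6 mice, 3 labelled NEGR1 overexpression and 3 control. NEGR1 (neuronal growth regulator 1) is a cell adhesion molecule of the IgLON family, anchored to the outer face of neuronal membranes. The study asked what raised NEGR1 does in relation to memory and to behaviour that models anxiety and depression. How the overexpression was brought about is not given in the sources used here. The 6 libraries held between 30726110 and 38108394 counts each, and 19354 genes had enough counts to be tested. Every library carried Y-linked transcripts, with Ddx3y at a normalised read count of 61.9 to 76.0 CPM, and little Xist, at 0.376 ± 0.0140 CPM in overexpression and 0.366 ± 0.194 CPM in control libraries. Values below are CPM after scaling with TMM factors, as mean ± SD with n = 3 per group, and fold changes are overexpression over control.

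Negr1 (ENSMUSG00000040037) stood at 193 ± 6.88 CPM (SD, n = 3) in the libraries labelled NEGR1 overexpression and at 176 ± 7.28 CPM (SD, n = 3) in the control libraries. The fold was 1.09, with a 95% interval of 1.01 to 1.19, and a log2 fold change of 0.13 ± 0.054 (SE). The 3 overexpression libraries had 185, 199 and 195 CPM of Negr1 and the 3 control libraries 181, 168 and 180 CPM, so the groups did not overlap. In edgeR's quasi-likelihood test Negr1 did not pass the threshold, with an adjusted p of 0.488 and an unadjusted p of 0.0309. A two-sided exact permutation test on log2 CPM gave p = 0.1, the smallest value that 3 libraries against 3 allow. The 4 other IgLON genes, which encode adhesion molecules of the same family, did not pass the threshold either. Lsamp was at 524 ± 14.97 against 515 ± 28.2 CPM, Opcml at 322 ± 18.6 against 330 ± 23.8 CPM, Ntm at 119 ± 10.7 against 126 ± 7.02 CPM and Iglon5 at 20.3 ± 0.301 against 22.0 ± 1.46 CPM. Their edgeR adjusted p-values lay between 0.665 for Iglon5 and 0.917 for Lsamp.

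The comparison of overexpression with control gave 9 genes past an adjusted p of 0.05, 5 higher and 4 lower. The 5 higher genes included Mx1, an antiviral GTPase, Tgtp1, an interferon-induced GTPase, and Cxcl9, a chemokine induced by interferon-gamma. Mx1 rose 4.66-fold, from 0.558 ± 0.0655 to 2.62 ± 0.954 CPM, Tgtp1 rose 5.24-fold, from 0.305 ± 0.0829 to 1.59 ± 0.306 CPM, and Cxcl9 rose 12.1-fold, from 0.154 ± 0.0649 to 1.85 ± 1.01 CPM. Ifi213, of the interferon-inducible p200 family, rose 4.77-fold and Fgl2, a fibrinogen-like protein made by immune cells, rose 1.81-fold, from 3.66 ± 0.0906 to 6.64 ± 0.698 CPM. The 4 lower genes were Cd5l, a secreted macrophage protein, Gpnmb, a glycoprotein of phagocytes, Fth1, the heavy chain of ferritin, and Atp6v0d2, a subunit of the vacuolar proton pump.

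Cd5l had 1 count in the 3 overexpression libraries together and 166 in the 3 control libraries. The control-to-overexpression ratio was 172, with an exact Clopper-Pearson 95% interval of 30.4 to 6831 that covers counting error only. Gpnmb fell to 0.267 times the control level, from 17.2 ± 4.12 to 4.60 ± 0.771 CPM, and Fth1 to 0.810 times, from 1503 ± 46.0 to 1218 ± 8.34 CPM. Atp6v0d2, named after its values were seen because its mean was below 1 CPM in both groups, had 8 counts against 84. In edgeR's test the adjusted p was 4.48e-04 for Cd5l, 0.0123 for Gpnmb, 0.0159 for Tgtp1 and Mx1, 0.0189 for Cxcl9 and Atp6v0d2, 0.0453 for Fth1 and 0.0499 for Ifi213 and Fgl2. For each of the 9 genes the 3 overexpression libraries lay on one side of the 3 control libraries. Groups did not overlap for 15.1% of tested genes, where chance gives 10% for 3 against 3, and 1788 genes had an unadjusted p under 0.05. Chance would give 967.7 on average, and the highest of the 9 other splits of the 6 libraries into 3 and 3 gave 1638. Values of Tgtp1, Ifi213 and Fth1 are uncertain, because they have near-identical genes or pseudogenes and how shared reads were counted is not given in the sources used here; Tgtp2, the near copy of Tgtp1, was at 1.68 ± 0.812 against 0.738 ± 0.289 CPM (adjusted p = 0.393).

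**Figure D1:**
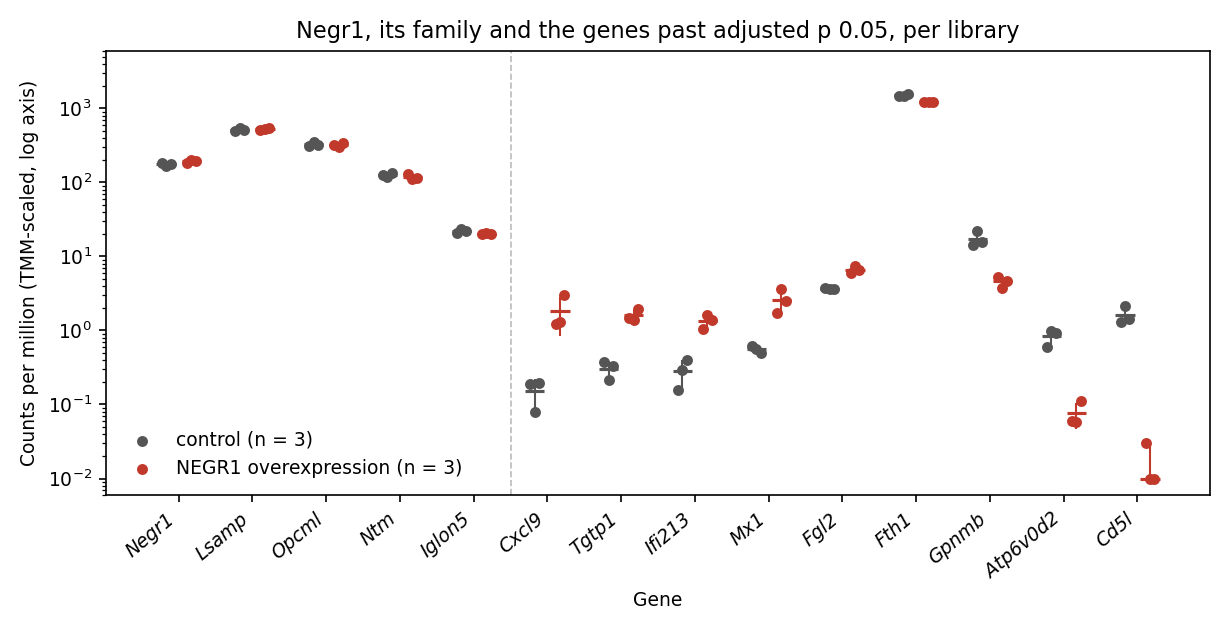
CPM (log axis) of Negr1, the 4 other IgLON genes and the 9 genes past an adjusted p of 0.05, with 1 point per library (n = 3 per group), bars at the group mean and vertical lines of 1 SD. The lowest position drawn, 0.01 CPM, stands for a count of 0 (Cd5l in 2 overexpression libraries); Negr1 lies at 168 to 199 CPM in all 6 libraries.

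The number of genes called rested on single libraries. It was 63 without overexpression replicate 1, 5 without overexpression replicate 2, 7 without overexpression replicate 3, 39 without control replicate 1, 2 without control replicate 2 and 3 without control replicate 3. Cd5l passed in all 6 of these fits and Gpnmb in 5, with an adjusted p of 0.106 without overexpression replicate 3. Cxcl9 passed in 4, Tgtp1 and Mx1 in 3, Fth1 and Atp6v0d2 in 2, and Ifi213 and Fgl2 in 1, with largest adjusted p-values of 0.256, 0.179, 0.179, 0.267, 0.232, 0.391 and 0.391 in that order. Over these fits the log2 fold changes kept their direction. They were 3.05 to 3.82 for Cxcl9, 2.17 to 2.57 for Tgtp1, 1.92 to 2.44 for Mx1, 1.98 to 2.54 for Ifi213 and 0.77 to 0.92 for Fgl2. The lower genes were at -8.80 to -6.47 for Cd5l, -2.02 to -1.69 for Gpnmb, -0.32 to -0.28 for Fth1 and -3.73 to -3.22 for Atp6v0d2. DESeq2's Wald test called 103 genes, among them all 9, and limma-voom with sample weights called 6, without Cxcl9, Ifi213 and Fgl2.

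Interferon-inducible genes were higher as a group in the overexpression libraries. All 25 members of the interferon response list had a fold change above 1, with a median log2 fold change of 0.60, and 12 had groups that did not overlap. Mx1 alone passed over all genes tested, and 18 of the 25 passed when adjusted over the list alone. The list passed limma's camera test with the preset correlation (adjusted p = 4.4e-22) and did not pass with an estimated one (adjusted p = 0.597 with an estimated correlation). The libraries differed within groups: the mean log2 deviation of the list was 0.093, 0.42 and 0.53 in overexpression replicates 1, 2 and 3, and -0.52, -0.46 and -0.069 in control replicates 1, 2 and 3. The exact permutation p of the list mean was 0.1, the smallest possible.

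Of 43 gene lists fixed before the data were examined, 18 passed camera with the preset correlation, 14 higher and 4 lower, and 0 passed with the estimated correlation, where the smallest unadjusted p was 0.0357. The 9 other splits of the 6 libraries into 3 and 3 gave 12 to 20 lists past the threshold with the preset correlation. Over the 18 lists the exact permutation p of the list mean ran from 0.1, the smallest possible, to 0.7 for cholesterol synthesis. It was 0.1 in the interferon, choroid plexus, thalamus and stress receptor lists and larger in the others. limma's fry, which tests a list without comparing it with other genes, called 0 lists for a move in 1 direction (smallest adjusted p = 0.549) and 0 for change in either direction (smallest adjusted p = 0.363).

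Myelin genes were lower as a group. Of 16 members of the oligodendrocyte and myelin list 15 had a fold change below 1, with a median log2 fold change of -0.35, and 8 passed when adjusted over the list alone, 0 over all genes. The camera adjusted p was 6.17e-12 with the preset correlation, and the adjusted p = 0.597 with an estimated correlation. Mbp, myelin basic protein, was at 1492 ± 121 against 2030 ± 220 CPM (adjusted p = 0.15) and Mag, myelin-associated glycoprotein, at 90.6 ± 6.82 against 127 ± 18.6 CPM (adjusted p = 0.232). Control replicate 1 lay beside the overexpression libraries on this list, at a mean log2 deviation of -0.089, where the other control libraries were at 0.36 and 0.20. The ependyma and cilia list was lower too, with 10 of 13 members below 1 and a median of -0.27 (camera adjusted p = 0.0121; adjusted p = 0.715 with an estimated correlation). It had 0 members past the threshold, adjusted over the list alone or over all genes, with Enkur at 1.80 ± 0.752 against 2.79 ± 0.528 CPM and Tekt1 at 1.83 ± 0.2996 against 2.50 ± 0.370 CPM. Its median was -0.033 without control replicate 2 (adjusted p = 0.839), -0.19 without overexpression replicate 3 (adjusted p = 0.0949), -0.18 without overexpression replicate 2 and -0.41 without control replicate 1 or 3.

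Genes of the meninges and choroid plexus, tissues that border the hippocampus, and genes of vessel walls were higher as groups. In the fibroblast and meninges list 15 of 16 members were above 1, with a median log2 fold change of 0.64, and 5 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 1.77e-11; adjusted p = 0.597 with an estimated correlation). The collagen genes Col1a1 and Col1a2 were at 11.3 ± 1.28 against 7.003 ± 1.62 CPM and at 22.5 ± 3.26 against 11.9 ± 2.94 CPM, with adjusted p-values of 0.189 and 0.215. Overexpression replicate 3 lay below control replicate 1 on this list, at a mean log2 deviation of -0.011 against 0.14. All 16 tested choroid plexus genes were above 1, with a median of 2.38, and 0 passed adjusted over the list alone (camera adjusted p = 1.45e-07; adjusted p = 0.597 with an estimated correlation). Overexpression replicate 1 set this value: without it the median was 0.44 (0.84 in all 6 libraries when only genes at 1 CPM or more in 3 libraries were kept), and Ttr, the transthyretin gene of the choroid plexus, was at 640 CPM there and at 3.08 to 38.3 CPM in the other 5 libraries. Otx2, a transcription factor of that tissue, was at 1.71 ± 1.78 against 0.289 ± 0.00791 CPM and Trpm3, an ion channel, at 129 ± 12.4 against 110 ± 2.78 CPM. The pericyte and smooth muscle list had 9 of 11 members above 1 and a median of 0.26 (camera adjusted p = 0.00214; adjusted p = 0.597 with an estimated correlation), with Des at 2.47 ± 0.824 against 1.57 ± 0.584 CPM and Vtn at 73.8 ± 9.45 against 64.3 ± 7.68 CPM. It had 0 members past the threshold over all genes or adjusted over the list alone, and overexpression replicate 3 again lay below control replicate 1, at -0.069 against 0.30. It did not pass without overexpression replicate 2 (adjusted p = 0.0607), and its median was 0.14 without control replicate 3.

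**Figure D2:**
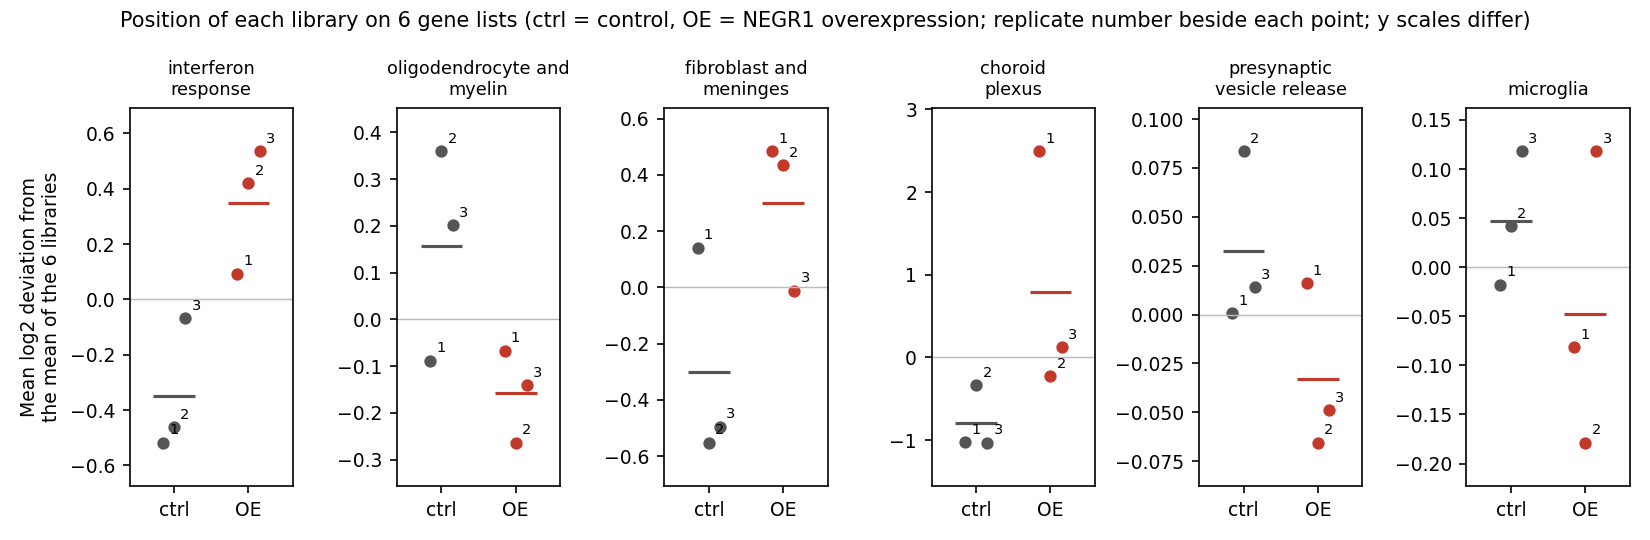
Mean log2 deviation of each library from the mean of the 6 libraries for 6 gene lists, 1 panel per list, with a point per library, its replicate number beside it and a bar at the group mean (n = 3). Overexpression replicate 1 stands at 2.49 on the choroid plexus list, and control replicate 1 at -0.089 on the myelin list.

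Synaptic vesicle genes were lower by a small amount, with groups that overlapped. On the presynaptic list overexpression replicate 1 was at a mean log2 deviation of 0.016, above control replicates 1 and 3 at 7.6e-04 and 0.014. Control replicate 2 was the highest, at 0.083, and the exact permutation p of the list mean was 0.3. The presynaptic vesicle release list had 24 of 28 members below 1, with a median log2 fold change of -0.067, and 0 members passed over all genes or adjusted over the list alone (camera adjusted p = 0.00152; adjusted p = 0.597 with an estimated correlation). Syp, the vesicle protein synaptophysin, was at 784 ± 28.1 against 882 ± 18.9 CPM (adjusted p = 0.34) and Rab3a, a vesicle GTPase, at 348 ± 13.8 against 379 ± 11.4 CPM (adjusted p = 0.488). Without control replicate 2 the median was -0.039 and the list did not pass (adjusted p = 0.0957). After a correction for GC content, added after the data were seen, the median was -0.027, with 11 members above 1 in place of 4 (adjusted p = 0.0168). The 5 lists of AMPA and kainate, NMDA, metabotropic glutamate and GABA-A receptors and of the postsynaptic scaffold did not pass, with camera adjusted p-values of 0.393 to 0.968. For the AMPA and kainate list and the metabotropic list the medians were 0.018 and 0.040 while the test statistic pointed lower. The stress and monoamine receptor list had 16 of 23 members above 1 and a median of 0.15 (camera adjusted p = 0.0469; adjusted p = 0.597 with an estimated correlation). In it the serotonin receptor gene Htr1a was at 46.9 ± 2.07 against 40.8 ± 0.825 CPM and Crhbp, which binds corticotropin-releasing hormone, at 21.1 ± 1.98 against 24.5 ± 1.39 CPM. In that list 0 members passed over all genes or adjusted over the list alone, and the list did not pass in 4 of the leave-one-out fits, without overexpression replicate 1 or 2 or control replicate 1 or 2 (largest adjusted p = 0.126; median 0.087 without overexpression replicate 1). It did not pass after the GC correction either, where the median was 0.14 and the SD over members 0.21 as before, since its adjusted p lay close to the threshold and became 0.0617.

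Markers of regions within and around the hippocampus were higher in 4 lists. The dentate gyrus granule cell list had all 16 members above 1, with a median log2 fold change of 0.23 (camera adjusted p = 0.00152; adjusted p = 0.715 with an estimated correlation), with Pdzd2 at 81.1 ± 10.3 against 68.4 ± 4.16 CPM and Ahcyl2 at 274 ± 14.2 against 251 ± 1.999 CPM. The ventral hippocampus pyramidal cell list had 16 of 20 above 1 and a median of 0.16 (camera adjusted p = 0.00182; adjusted p = 0.597 with an estimated correlation), with Etv1 at 162 ± 4.55 against 139 ± 8.11 CPM and Coch at 5.42 ± 1.55 against 3.45 ± 0.662 CPM. The thalamus and habenula list had 13 of 15 above 1 and a median of 0.15 (camera adjusted p = 0.00152; adjusted p = 0.597 with an estimated correlation), with Zic1 at 14.7 ± 1.45 against 10.1 ± 1.27 CPM and Synpo2 at 12.1 ± 0.804 against 9.09 ± 1.97 CPM. The cortex layer list had 11 of 16 above 1 and a median of 0.074 (camera adjusted p = 0.0405; adjusted p = 0.597 with an estimated correlation), with Foxp2 at 2.58 ± 0.437 against 1.52 ± 0.217 CPM and Rorb at 26.5 ± 1.41 against 22.7 ± 1.16 CPM. Adjusted over the list alone, 0, 1, 1 and 3 members passed in these 4 lists, and 0 over all genes. On the dentate list overexpression replicate 1 was the lowest of the 6 libraries, at a mean log2 deviation of -0.34. The dentate median was 0.42 without that library, and the list did not pass without overexpression replicate 2 (median 0.073, adjusted p = 0.421) or 3 (median 0.13, adjusted p = 0.0564). The pyramidal list did not pass without control replicate 2 (median 0.060, adjusted p = 0.155), and its median was 0.081 without overexpression replicate 1. Its groups overlapped, with overexpression replicate 3 at a mean log2 deviation of -0.084 and control replicates 1 and 3 at 0.048 and -0.081. The exact permutation p of the list mean was 0.4 for dentate, 0.3 for pyramidal, 0.1 for thalamus and 0.3 for cortex genes. The thalamus median was 0.090 without overexpression replicate 3, 0.24 without overexpression replicate 1 and 0.094 after the GC correction. The cortex list did not pass without overexpression replicate 1 (median 0.027, adjusted p = 0.542) or control replicate 2 or 3 (adjusted p = 0.0514 and 0.132).

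By list medians, protein folding genes and glucocorticoid responsive genes were higher and cholesterol synthesis genes lower, with groups that overlapped on each list. The exact permutation p of the list mean was 0.2, 0.5 and 0.7 in that order. Overexpression replicate 1 was the highest of the 6 libraries on the cholesterol list, at a mean log2 deviation of 0.074. The heat shock and unfolded protein response list had 21 of 25 members above 1 and a median log2 fold change of 0.15 (camera adjusted p = 2.93e-06; adjusted p = 0.597 with an estimated correlation). Hsp90b1, a chaperone of the endoplasmic reticulum, was at 337 ± 34.0 against 277 ± 19.5 CPM and Manf, a secreted stress factor of that compartment, at 48.3 ± 7.15 against 38.2 ± 2.06 CPM. The median of this list was 0.070 without overexpression replicate 3. Of the cholesterol synthesis genes 20 of 23 were below 1, with a median of -0.073 (camera adjusted p = 0.00586; adjusted p = 0.715 with an estimated correlation), with Dhcr7 at 27.6 ± 2.89 against 32.1 ± 0.590 CPM and Insig1 at 42.3 ± 6.01 against 48.9 ± 2.65 CPM. Glucocorticoid responsive genes had a median of 0.098, with 13 of 14 above 1 (camera adjusted p = 0.00783; adjusted p = 0.715 with an estimated correlation). In that list Klf9 was at 254 ± 12.4 against 236 ± 5.63 CPM and Sult1a1 at 11.2 ± 1.03 against 8.95 ± 1.61 CPM, and the median turned to -0.016 without control replicate 2 (adjusted p = 0.911). It was 0.070 without overexpression replicate 3 (adjusted p = 0.0972), 0.20 without control replicate 1 and 0.15 without control replicate 3. Adjusted over the list alone, 1 heat shock gene passed and 0 of the cholesterol and glucocorticoid lists, and 0 over all genes in any of them. Cholesterol synthesis did not pass without overexpression replicate 3 (median -0.021, adjusted p = 0.474) or control replicate 2 (median -0.078, adjusted p = 0.0957), and its median was -0.14 without overexpression replicate 1 and -0.12 without control replicate 1.

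Lists of respiratory chain and ribosomal genes passed as higher, by small medians and with members in both directions. On the mitochondrially encoded list overexpression replicate 2 was at a mean log2 deviation of 0.43, and replicates 1 and 3 at -0.16 and -0.044. Control replicates 1, 2 and 3 were at 0.026, -0.25 and -0.0063. The exact permutation p of the list mean was 0.6 for mitochondrially encoded, 0.3 for ribosomal and 0.2 for nuclear oxidative phosphorylation genes. The 13 mitochondrially encoded genes had a median log2 fold change of 0.11, 12 of them above 1, with mt-Co2 at 85.1 ± 11.4 against 67.6 ± 6.75 CPM and mt-Nd6 at 1126 ± 39.0 against 1036 ± 69.4 CPM (camera adjusted p = 0.00623; adjusted p = 0.715 with an estimated correlation). The 13 genes together held 3.90 to 4.54% of the counts of a library, of which mt-Co2 was a very small part. Its value is uncertain, because how reads shared between genes were counted is not given. Of 49 cytosolic ribosomal protein genes 30 were above 1, with a median of 0.043 (camera adjusted p = 0.0373; adjusted p = 0.715 with an estimated correlation), and Rps19 was at 55.7 ± 3.14 against 44.5 ± 2.67 CPM and Rps28 at 11.9 ± 1.35 against 8.51 ± 1.18 CPM. Of 57 nuclear oxidative phosphorylation genes 32 were above 1, with a median of 0.016 (camera adjusted p = 0.0405; adjusted p = 0.715 with an estimated correlation), and Uqcr10 was at 27.6 ± 0.534 against 22.8 ± 0.929 CPM and Cox6c at 82.4 ± 3.52 against 71.9 ± 2.16 CPM. This last call needed the matching of older gene symbols, which was added after a first look at the data: without it 17 lists passed and this one did not. Adjusted over the list alone, 0, 2 and 0 members passed in these 3 lists, and 0 over all genes. Each lost its call without overexpression replicate 2, with medians of 0.035, 0.019 and -0.0028 and adjusted p-values of 0.482, 0.342 and 0.471. The mitochondrially encoded list also lost it without control replicate 2 (median 0.042, adjusted p = 0.467) and after the GC correction, where the median was 0.027, 8 of 13 genes were above 1 and the SD over members was 0.42 against 0.41 before (adjusted p = 0.743). The ribosomal list lost it without overexpression replicate 3 (median 0.021, adjusted p = 0.0972) or control replicate 1 (median 0.014, adjusted p = 0.205). The oxidative phosphorylation list lost it without control replicate 1 or 3 (medians 0.016 and 0.025, adjusted p = 0.219 and 0.0765). Its median was 0.031 without overexpression replicate 1 or 3 and 0.034 without control replicate 2 or after the GC correction.

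**Figure D3:**
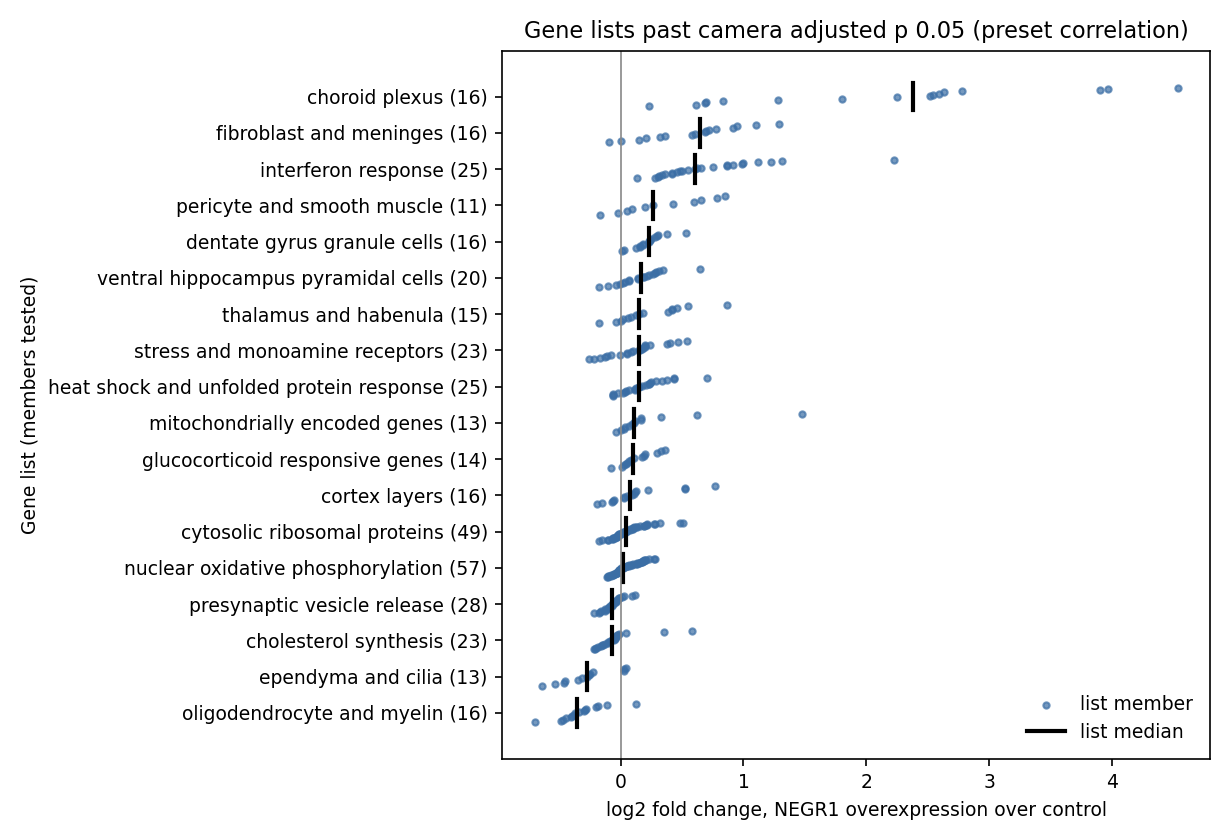
log2 fold change (overexpression over control) of each tested member of the 18 lists past a camera adjusted p of 0.05 with the preset correlation, with a black bar at the list median. Medians run from -0.35 for oligodendrocyte and myelin genes to 2.38 for choroid plexus genes.

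The 25 lists that did not pass had camera adjusted p-values of 0.0626 to 0.968. They included microglia, with a median log2 fold change of -0.029 and 11 of 16 members below 1. The microglia list leaned lower (camera adjusted p = 0.082; adjusted p = 0.715 with an estimated correlation), and 1 member, a lower one, passed adjusted over the list alone. Among the others were astrocytes (median -0.026), GABAergic interneurons (0.028), CA1 pyramidal cells (-0.0099), immediate early genes (-0.056), inflammation and complement (0.037) and the IgLON family (-0.036). Fold changes also followed GC content across genes, with Spearman's rho of -0.286 over 15814 genes, which are not independent replicates; the median log2 fold change was 0.061 in the fifth of genes lowest in GC and -0.052 in the highest. The trend was not the same in all libraries: the rho of GC content with the library's deviation was -0.399 in overexpression replicate 3, 0.318 in control replicate 1 and 0.227 in control replicate 3. It was -0.030 and 0.026 in overexpression replicates 1 and 2 and -2.71e-04 in control replicate 2. After the correction for GC content 7 genes passed, without Ifi213 and Fgl2. The log2 fold change of Ifi213 went from 2.25 ± 0.36 (SE) to 2.19 ± 0.36 and that of Fgl2 from 0.86 ± 0.14 to 0.80 ± 0.14. Both adjusted p-values had been 0.0499, just under the threshold, and became 0.0668 and 0.116.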

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

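The GC correction and the matching of list symbols without synonyms were chosen after seeing the data; all other alternatives were set before. The count of 9 genes was 9 with DESeq2 size factors, upper quartile factors, and scaling without Negr1 and mitochondrial genes. It was 103 with DESeq2's Wald test, 304 with no filter on low counts, 5 with at least 1 CPM in 3 libraries (a filter that removes low genes), 26 with the replicate block, 19 at an adjusted p under 0.1, 6 with limma-voom weights, 7 with GC correction, and 2 to 63 over the leave-one-out fits; the cause of these differences was not tested. Same-numbered libraries had deviation correlations of 0.014, 0.019 and 0.018, against -0.029 to 0.011 for the other pairs across groups. These small values do not settle whether the numbers pair the samples. With the replicate block, 8 of the 9 genes were among the 26. Negr1's log2 fold change was 0.086 to 0.14 over the other alternatives (adjusted p 0.443 to 0.74) and 0.095 to 0.16 over the leave-one-out fits. Negr1 did not pass the threshold in any of them. The 18 lists became 0 with the estimated correlation, 0 with fry in its directional form and 0 in its mixed form. The estimated correlation was far above the preset one in the interferon (0.497), myelin (0.837), fibroblast (0.70) and choroid plexus (0.93) lists. Camera also uses fewer degrees of freedom when it estimates the correlation, which raises p by itself. How much each of these accounts for a loss was not tested, and correlation between members did not explain each of them. The stress and monoamine receptor list had an estimated correlation of -0.018, below the preset 0.01. Its unadjusted camera p still went from 0.0196 to 0.0615. The count was 18 with DESeq2 size factors and with the strict filter, 20 with the replicate block (where the stress and monoamine receptor list had an adjusted p of 0.0505), 19 with GC correction, 17 without synonyms, and 11 to 21 over the leave-one-out fits, with 6 lists past the threshold in every one (interferon, myelin, fibroblast, choroid plexus, thalamus, heat shock). Among called lists, the glucocorticoid median turned without control replicate 2 (-0.016 to 0.20 over the leave-one-out fits) and the oxidative phosphorylation median without overexpression replicate 2 (-0.0028 to 0.034). The other values that reversed belonged to genes past no threshold. Lsamp was -0.011 with GC correction. Over the leave-one-out fits Opcml ran from -0.077 to 0.022, Xist from -0.25 to 0.55, Uty from -0.14 to 0.027 and Kdm5d from -0.016 to 0.12. Xist and Eif2s3y were -0.039 and -0.0012 with GC correction.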

Other observations

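Some tests in this part were chosen after the result they measure had been seen: those on swapped labels, on a single deciding library, on more or fewer microglia, on white matter and on interferon-gamma inducible genes. The margins of error applied to the bounds were also set after the values were seen. The 6 gene lists used here were written after the main results; their camera p-values are adjusted over these 6 and are not independent evidence of the patterns that prompted them. The interferon lists, the damage-associated list and the lysosomal list passed with the preset correlation, and 0 of the 6 did with an estimated one.

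Further genes of activated microglia and astrocytes, named after their values were seen, lay between an adjusted p of 0.05 and 0.1 in edgeR's test. Itgax, an integrin of activated microglia, was at 1.197 ± 0.488 against 4.07 ± 0.994 CPM, and Cd68, a lysosomal protein of phagocytes, at 7.14 ± 0.809 against 11.1 ± 0.497 CPM. Gfap, the astrocyte filament protein, was at 356 ± 39.9 against 508 ± 37.2 CPM, with an adjusted p of 0.0862 for each of the 3 genes. In the reactive astrocyte list, which holds Gfap, 9 of 15 members were above 1, with a median log2 fold change of 0.068 (camera adjusted p = 0.559). Gbp10, a guanylate-binding protein induced by interferon, was at 1.07 ± 0.628 against 0.134 ± 0.0590 CPM (adjusted p = 0.0862). A list of 19 other damage-associated microglial genes, with 16 members below 1, had a median log2 fold change of -0.15 (camera adjusted p = 2.83e-07; adjusted p = 0.0692 with an estimated correlation). The median was -0.24 without overexpression replicate 1 and -0.26 without overexpression replicate 3, which stood at a mean log2 deviation of 0.029 where overexpression replicates 1 and 2 were at -0.14 and -0.48. In it Lyz2 was at 9.84 ± 4.12 against 19.9 ± 1.599 CPM and Apoe at 1123 ± 51.2 against 1316 ± 38.4 CPM. Of 30 type I interferon inducible genes 29 were above 1, with a median of 0.53 (camera adjusted p = 9.6e-20; adjusted p = 0.0692 with an estimated correlation). The monocyte and border macrophage list had 8 of 12 members above 1 and did not pass (camera adjusted p = 0.226; adjusted p = 0.38 with an estimated correlation). With no filter on low counts it passed, over 16 members with a fitted median of 0.39 (adjusted p = 0.0442, where the 13 alternatives ran from 0.0442 to 0.681). Of 22 lymphocyte genes 7 were tested, 2 of them at 1 CPM or more in the controls, and the list did not pass (camera adjusted p = 0.226; adjusted p = 0.38 with an estimated correlation). In it Ighm, an antibody heavy chain gene, was at 8.77 ± 4.67 against 5.54 ± 0.259 CPM. Igkc, an antibody light chain gene outside the list, was 16.0-fold higher, at 2.79 ± 2.23 against 0.176 ± 0.132 CPM, with groups that did not overlap (adjusted p = 0.444).

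Negr1 was 1.09-fold higher in libraries labelled overexpression, without passing the threshold. A swap among these 6 libraries would leave at least 1 library far above the others if the raised Negr1 were counted, and the highest was 1.08 times the median of the 6. Scaling does not account for the small size, as the highest log2 fold change over the scaling alternatives was 0.14. A candidate explanation that stays open, untested, is that the added transcript differs from the counted one or was raised in few of the sampled cells. These counts do not show that NEGR1 was raised in these samples, so differences between the groups cannot be assigned to raised NEGR1.

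Interferon-inducible genes were higher in the overexpression libraries. More microglia would raise their own markers too, and the microglia list had a median log2 fold change of -0.029 with an upper quartile of 0.034. No single library accounted for the median, whose lowest value over the leave-one-out fits was 0.45, without overexpression replicate 3, but grouping overexpression replicate 1 with control replicates 1 and 2 gave 0.60 in size, as the labels did. More lymphocytes cannot be told apart. The list's median was 0.19 over 7 genes, below the bound set beforehand against this explanation, but not by the margin added after the values were seen. That margin was 0.13, the SE of the list mean over genes, which does not measure error between libraries. The median was 0.030 without overexpression replicate 3, 0.11 without control replicate 2 and 0.33 without overexpression replicate 2. It was 0.61 by fitted values over all 22 genes with no filter on low counts, a setting that adds genes near the floor (camera adjusted p = 0.041, where the 12 alternatives ran from 0.041 to 0.681). Interferon-gamma inducible genes were higher as well, 20 of 22 above 1 with a median of 0.60 (camera adjusted p = 3.49e-10; adjusted p = 0.172 with an estimated correlation), but overexpression replicate 3 stood apart at a mean log2 deviation of 0.79 against 0.041 and 0.080 and the median was 0.39 without it, so a response to interferon may be one hypothesis, with its source, including delivery of the gene, untested.

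Cd5l, Gpnmb and Atp6v0d2, genes of phagocytes, were lower in the overexpression libraries. Fewer microglia would lower the microglia list as far, and its lower quartile was -0.17 while the median of the 3 genes was -3.38 by fitted values. Less white matter was taken to lower them no further than myelin, and the lowest myelin gene, Opalin, was at -0.70 ± 0.28 (SE) against -1.90 ± 0.18 for Gpnmb. The 3 genes were picked from these data as calls that fell, so a fall beyond a list written beforehand was partly built in. The 3 genes fell further than the members of either list, but neither comparison can exclude fewer microglia or less white matter. The other damage-associated genes went the same way (-0.15), but 2 of the 9 other splits of the libraries gave a larger median in size (0.22 and 0.16), so a lower phagocytic state is no more than a hypothesis. Whether lysosomal genes are lower in general cannot be told apart, because the outcomes set beforehand for and against it both held: the list passed camera, with 23 of 30 below 1 (adjusted p = 3.6e-05; adjusted p = 0.204 with an estimated correlation), and its median of -0.076 lay above -0.1 (-0.11 without overexpression replicate 1 and -0.041 without overexpression replicate 2).

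The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As many genes as the real 9 came from 1 of the 10, the real one, and the highest of the others gave 5. As many lists as the real 18 came from 4 of the 10, and the 9 others gave 12 to 20. The myelin list median was -0.35 in the real split and 0.35 in size with overexpression replicate 1 grouped with control replicates 2 and 3.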
